A study of Homo sapiens with 5 samples.

How the data were processed

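Gene expression was measured in NB4 cells infected with a SALL4 shRNA retrovirus (2 arrays) or with the empty vector (2 arrays), and SALL4 occupancy was measured by ChIP-chip on 1 two-colour promoter array. Groups were taken from the sample titles. Replicate numbers only name the arrays. The channels of the ChIP array were taken from their source names, with SALL4 in Cy3 and IgG in Cy5 per the labels.

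The intensity values of both kinds of array are probe signals that the authors deposited as read by NimbleScan, version 2.3.78 for expression and 2.3.31 for ChIP-chip, per the file headers. Whether a background was subtracted is not given in the sources used here. The expression array carries 8 probes for nearly every one of 47633 transcripts and 7500 random-sequence control probes, designed on hg18 (NCBI Build 36) per the labels. RNA had been converted to labelled double-stranded cDNA, per the labels' protocols. The authors' deposited table of normalized intensity per transcript is on a linear scale, with medians of 469 and 184 on shRNA arrays 1 and 2 and 421 and 184 on control arrays 1 and 2. Its normalization method is unknown. The deposited call files hold the mean probe intensity of each transcript. The authors' deposited ChIP values are log2 ratios with a median of -0.01. Set against the probe signals they are Cy5 over Cy3, and how they were centred is unknown.

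The dates in the file headers placed shRNA replicate 1 with control replicate 1 (set 1) and shRNA replicate 2 with control replicate 2 (set 2). Whether these are dates of scanning is not known. The 381002 transcript probes shared by the 4 arrays and the control probes were background-corrected with normexp (offset 50), quantile normalized, put on a log2 scale and averaged per transcript (limma 3.58.1 in R 4.3.3, data.table version 1.17.8). Transcripts above the 95th percentile of the random-sequence probes on at least 2 of the 4 arrays were kept, which left 41255 transcripts of 22721 genes. Above that percentile were 70.8% and 67.3% of transcripts on shRNA arrays 1 and 2 and 95.9% and 82.2% on control arrays 1 and 2. Pearson correlations across transcripts, which are not independent replicates, were 0.97 between the shRNA arrays, 0.95 between the control arrays, 0.96 within set 1 and 0.93 within set 2. Across the sets they were 0.87 between shRNA array 1 and control array 2 and 0.96 between control array 1 and shRNA array 2. Control array 1 was thus no closer to control array 2 than to either shRNA array.

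Each transcript was tested two-sided with limma's lmFit and eBayes, with the set as a block and Benjamini-Hochberg adjustment over all kept transcripts at 0.05. A gene was represented by its transcript with the highest mean signal. A transcript not above background on either array of a group has only a bound there, given as at least N-fold: the brighter group's mean against the mean, per array, of the higher of the background level and the transcript's own normalized log2 signal. Of 23711 Entrez gene identifiers on the array, 20261 matched the RefSeq table used for current symbols, and the others kept the name in the files.

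The 27 gene lists were tested with camera (preset correlation 0.01, two-sided, adjusted over the lists, at least 5 measured genes) and again with an estimated correlation. The lists, main tests, alternatives and the rule for named genes were fixed before the data were examined, except for choices marked below as made after results were seen. That rule took SALL4, the 10 largest rises and 10 largest falls past the threshold that moved the same way in both sets, up to 4 members of each list past the threshold, the apoptosis genes linked to SALL4, the 20 nameable promoters with the highest ratio, and the 10 genes with the highest ratio among the top 500 promoters whose transcript passed. The values of some genes under this rule are not reported here.

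For ChIP-chip, log2 of Cy3 over Cy5 of 386230 promoter probes was centred on the array's median, with no loess. The channel medians were 1775 for Cy3 and 816 for Cy5, and on 3077 random-sequence probes 822 and 219. The highest and the lowest mean over 500 bp windows with at least 4 probes were taken per region, and regions at or above 1 were counted beside those at or below -1. Regions were named through hg18 transcript starts in the deposited expression files, which gave 16271 regions 1 gene, 1246 several and 511 none. List medians were set against 10000 random lists matched on probe number and mean intensity. The top 500 promoters were compared in expression with all other genes measured by both assays (camera).

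Tested on simulated data, the expression test called 22% of log2 changes of 0.6 and 95% of 1.2 among 41255 transcripts, and the ChIP count found 97% of raised regions and 0.21% of others. The simulated ChIP probes varied independently, with an SD of 0.63 and no trend with brightness. On the real array neighbouring probes correlated at 0.36 and the ratio varied with brightness, so 0.21% is not its rate of false calls. Alternatives changed the block, background correction, normalization, probe summary, filter, source of values, transcript choice, list test, promoter ranking, windows, thresholds and arrays included. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the ChIP counts and the figures.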

Results

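The series measured 2 things in NB4, a human cell line derived from an acute promyelocytic leukaemia. SALL4, a zinc finger transcription factor of embryonic stem cells that is also found in leukaemia cells, was immunoprecipitated from untreated NB4 cells, and the recovered DNA was hybridised against an IgG control on 1 promoter tiling array. Separately, RNA from cells infected with a retrovirus carrying a short hairpin RNA (shRNA) against SALL4 and from cells infected with the empty vector was hybridised to 4 single-colour expression arrays, 2 per group. The arrays ask which promoters SALL4 occupies and which genes change when its level is reduced. By their header dates the expression arrays formed 2 sets, each with 1 shRNA and 1 control array. The change within each set is given beside the joint estimate for SALL4, the largest changes, the gene lists and their leading genes. Nothing in the labels states that the 2 arrays of a group came from separate infections, so the p-values cannot be taken to measure the spread between infections. In the main fit those of single transcripts rest on 1 variance shared by all transcripts, left after the differences between sets and groups. Those of the gene lists compare genes with other genes. The median raw probe signal was 478 and 491 on the shRNA arrays and 786 and 824 on the control arrays, in the order of replicates 1 and 2. Probes of random sequence had medians of 99.9 and 174 on the shRNA arrays and 138 and 289.5 on the control arrays. The number of arrays limits the precision of every value below.

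SALL4 itself was lower on the shRNA array than on the control array of both sets. The brighter of its 2 transcripts on the array (BC111714; chromosome 20, 49834026 to 49852406, hg18) had a normalized log2 signal of 8.14 ± 0.20 (SD, n = 2) after shRNA and 8.81 ± 0.45 (SD, n = 2) in the control, a 1.59-fold fall (log2 change -0.67, SE 0.20, adjusted p = 0.0043), with log2 changes of -0.49 in set 1 and -0.84 in set 2. The other, NM_020436, was not above the random-sequence probes on either shRNA array and was at least 1.24-fold lower (adjusted p = 0.051, not past the threshold). It passed with scaling to 1 median (adjusted p = 0.014), cyclic loess (0.025), no filter (0.036) and the authors' deposited normalized table (0.045). SALL4 lay near the background of the array. Among the 1000 transcripts closest to it in mean signal, the median log2 change was -0.10 with a 5th to 95th percentile range of -1.49 to 0.84, and the change of SALL4 stood at the 24.1th percentile. The fall was therefore no larger than that of many dim transcripts, and it checks the labels of the arrays only weakly. Without the set as a block the adjusted p of BC111714 was 0.33, and with Tukey's median polish its log2 change was -0.32 (adjusted p = 0.18). With the authors' deposited normalized table the change was -0.60 and did not pass (adjusted p = 0.10, limma). With 1 array left out, in the fit without the block, the change ran from -0.98 to -0.35 and passed in none of the 4 fits (adjusted p = 0.12 to 0.98, limma).

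Outside SALL4, with each gene represented by its brightest transcript, the largest rises on the shRNA arrays included genes for a histone H2A deubiquitinase, a kinase and ubiquitin ligases. The largest falls were in predicted genes and in members of the GAGE and REXO1L families. MYSM1, the deubiquitinase, was at 10.81 ± 1.07 (SD, n = 2) against 9.12 ± 1.29 (SD, n = 2), a 3.22-fold rise (adjusted p = 9.83e-15). AKT2, a serine/threonine kinase downstream of PI3K, rose 3.15-fold. RC3H1, an RNA-binding protein that promotes mRNA decay, rose 3.07-fold, and MBTD1, a reader of methylated histones, rose 3.06-fold. ADAM22, the predicted gene LOC645494, the ubiquitin ligase MIB1, VPS13B, the nuclear long non-coding RNA MALAT1 and the Wnt co-receptor LRP6 rose between 3.02-fold and 2.80-fold. Each of these moved the same way in both sets, which the rule for choosing them required. The other transcripts of MYSM1, RC3H1, MBTD1, ADAM22 and MIB1 also rose, by log2 changes of at least 0.57, as did 5 of the 6 VPS13B transcripts, 1 of them by 1.71. The log2 changes of these 10 genes ran from 1.14 (MIB1) to 1.65 (MALAT1) in set 1 and from 1.33 (MALAT1) to 2.09 (AKT2) in set 2. Without 1 of the arrays only the fit without the block can be tested, and it mixes the difference between the sets with the change. There, leaving out shRNA replicate 1 gave log2 changes of 0.17 (MALAT1) to 1.33 (ADAM22) and leaving out control replicate 2 gave 0.24 (MIB1) to 1.14 (ADAM22), with 0 of the 10 past the threshold each time (adjusted p = 0.39 to 0.99 and 0.44 to 0.94, limma). Without control replicate 1 the changes were 1.94 to 2.86 and 7 passed, and without shRNA replicate 2 they were 1.86 to 2.80 and 10 passed.

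The largest fall was that of LOC388259, a predicted gene on chromosome 16 (32972454 to 32986464), from 14.14 ± 0.03 (SD, n = 2) to 9.74 ± 0.21 (SD, n = 2), which is 21.2-fold (adjusted p = 2.11e-97). The predicted genes LOC644586 on chromosome 7, LOC221136 on chromosome 13 and LOC644813 on chromosome 4 had log2 changes of -3.91, -3.81 and -3.76. The other 6 were at positions in the GAGE cluster of cancer-testis antigen genes on chromosome X, where LOC645043, LOC645009, GAGE12G and GAGE7B fell 11.6-fold, 11.6-fold, 11.5-fold and 11.4-fold, and in the REXO1L pseudogenes on chromosome 8, where REXO1L5P and REXO1L6P fell 11.3-fold and 11.2-fold. GAGE12G and GAGE7B overlap in position and the members of both families are near-identical copies, so a single probe can detect several of them and the values cannot be assigned to 1 gene. The log2 changes of these 10 genes ran from -4.53 to -3.38 in set 1 and from -4.45 to -3.30 in set 2. The 18 transcripts of the GAGE family on the array had a median raw log2 difference, shRNA minus control, of -3.59 in set 1 and -3.03 in set 2. In raw signal other features were also lower on the shRNA arrays, with medians over all transcripts of -0.40 and -0.60 in sets 1 and 2. For 364 transcripts of single-copy olfactory and taste receptors the median raw log2 differences in sets 1 and 2 were -1.69 and -1.47, and for random-sequence probes they were -0.47 and -0.73. After normalization the receptors were still lower, at -0.72 and -0.92, but the random-sequence probes were higher, at 0.50 and 0.37. With 1 array left out, in the fit without the block, the 10 falls passed in 3 of the 4 fits, and without control replicate 2, where their log2 changes were -4.39 to -3.07, 1 passed (adjusted p = 0.043 to 0.067, limma).

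**Figure D1:**
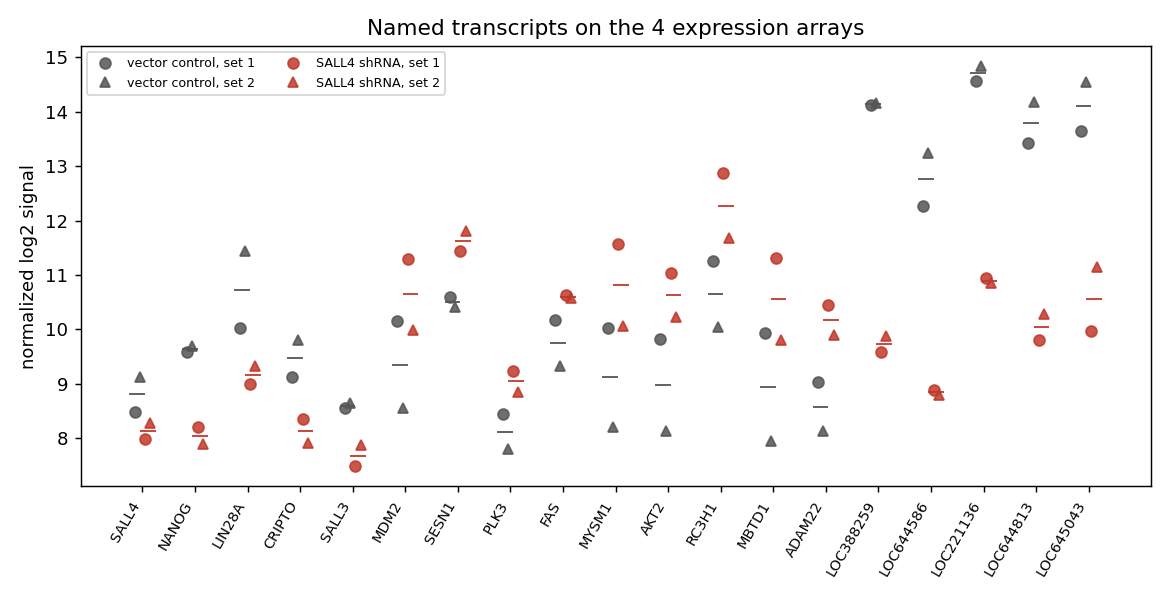
Normalized log2 signal (vertical axis) of SALL4, of the named pluripotency and p53 target genes and of the 5 largest rises and falls on each of the 4 expression arrays (grey, vector control; red, SALL4 shRNA; circles, set 1; triangles, set 2; bars, group means). In each set the SALL4 signal after shRNA lies below the control value, and LOC388259 falls from 14.14 to 9.74.

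Of 41255 transcripts above background, 9577 rose and 8317 fell at an adjusted p under 0.05 with the set as a block (limma), and 823 rose and 3095 fell at least 2-fold. The changes in the 2 sets correlated across transcripts (Pearson r = 0.84; transcripts are not independent replicates), and 82.8% of transcripts had the same sign in both. With the arrays paired across the sets r was 0.23. There the difference between the sets enters the 2 changes with opposite signs and lowers r, so 0.23 is not a chance level. The count of calls rests on 1 residual degree of freedom: limma put the same variance on every transcript, so every log2 change has the standard error 0.20. Without the block 0 transcripts passed, 7179 had an unadjusted p under 0.05, and the lowest adjusted p was 0.088. With 1 array left out, in that fit, between 1 (without control replicate 2) and 1777 (without control replicate 1) passed. When arrays were scaled to 1 median in place of quantile normalization, the median change of all transcripts was 0.58, against 0.12, and 22856 rose and 8455 fell. The direction of change varied with signal: 40.7% of transcripts with a mean log2 signal under 8 fell and 9.71% rose, whereas between 10 and 11 39.3% rose and 8.87% fell. Above that the share of rises dropped again, to 11.97% between 12 and 14, where 6.41% fell, and to 2.87% between 14 and 17, where 9.01% fell. Of the falls, 2484 were of transcripts with a mean log2 signal under 8 and 3300 between 8 and 9. Transcripts above background on the control arrays alone were tested too, so falls near background cannot be read as changes of expression alone. The transcripts that fell had median raw log2 differences of -1.68 and -1.46 in sets 1 and 2, against -1.69 and -1.47 for the single-copy receptors.

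Of 27 gene lists fixed beforehand, 4 were shifted upward and 1 downward relative to all other genes (camera, preset correlation). The test with an estimated correlation rests on the 1 residual degree of freedom of the arrays. With it the p of T cell markers went from 0.011 to 0.22 (camera), although their estimated correlation, -0.06, was below the preset 0.01. Its p-values therefore cannot decide between correlated genes and too few arrays. The list of p53 target genes was shifted upward: 11 of 26 measured genes rose, 0 fell and 15 did not pass (mean log2 change 0.38, adjusted p = 0.021; adjusted p = 0.78 with an estimated correlation). Rises were common at this brightness: the list had a mean log2 signal of 10.5, and 39.3% of all transcripts between 10 and 11 rose. MDM2, a RING-type ubiquitin ligase gene, rose 2.44-fold (log2 changes of 1.15 and 1.43 in sets 1 and 2), and all 17 of its transcripts on the array rose. SESN1, a stress-induced regulator of mTORC1 signalling, rose 2.16-fold, the kinase gene PLK3, above background on 1 of the 2 control arrays, rose 1.91-fold and the death receptor gene FAS rose 1.81-fold. Adjusted over the list alone, 11 rose. BBC3, which is in this list and encodes the pro-apoptotic protein PUMA, was at a log2 change of -0.46 and did not pass. DNA replication genes were also shifted upward: 8 of 36 rose, 0 fell and 28 did not pass (mean log2 change 0.32, adjusted p = 0.021; adjusted p = 0.78 with an estimated correlation). Their mean log2 signal was 12.3, and 11.97% of all transcripts between 12 and 14 rose. GINS1, a subunit of the replicative helicase complex, rose 1.85-fold (log2 changes of 0.70 and 1.08 in sets 1 and 2), cyclin E2 (CCNE2) 1.76-fold, the polymerase delta catalytic subunit POLD1 1.56-fold, and the origin recognition subunit ORC1 had a log2 change of 0.59, while PCNA, at a log2 change of -0.01, did not pass. Adjusted over the list alone, 6 rose.

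Both apoptosis lists were shifted upward with the preset correlation. The mean log2 signal was 10.96 for the pro-apoptotic and 11.6 for the anti-apoptotic list. Of all transcripts, 39.3% rose between 10 and 11 and 26.2% between 11 and 12. In the pro-apoptotic list 16 of 45 genes rose, 2 fell and 27 did not pass (mean log2 change 0.26, adjusted p = 0.029; adjusted p = 0.78 with an estimated correlation). BCL2L11, which encodes the BH3-only protein BIM, rose 1.83-fold by its brightest transcript (log2 changes of 0.86 and 0.88 in sets 1 and 2), FAS 1.81-fold, and the caspase genes CASP6 and CASP10 1.69-fold and 1.64-fold; 1 of the 7 transcripts of BCL2L11 and 1 of the 7 of CASP10 fell. The 2 genes that fell were HRK, at a log2 change of -0.99, and DAPK1, which was not above background on either shRNA array; both were chosen for mention after their values were seen. In the anti-apoptotic list 8 of 26 genes rose, 0 fell and 18 did not pass (mean log2 change 0.30, adjusted p = 0.040; adjusted p = 0.78 with an estimated correlation). The inhibitors of apoptosis NAIP and BIRC3 both rose 1.78-fold (NAIP by log2 changes of 0.75 and 0.91 in sets 1 and 2), the kinase gene PIM1 1.69-fold and CFLAR, which encodes the caspase-8 inhibitor FLIP, 1.62-fold. Adjusted over the list alone, 16 pro-apoptotic genes rose and 2 fell, and 8 anti-apoptotic genes rose.

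The list of SALL family and pluripotency factors was shifted downward: 10 of 15 measured genes fell, 0 rose and 5 did not pass (mean log2 change -0.61, adjusted p = 0.040; adjusted p = 0.78 with an estimated correlation). SALL4, the target of the shRNA, is itself in this list and among the genes that fell, so the shift is not independent of the knockdown. NANOG fell 3.03-fold (log2 changes of -1.39 and -1.81 in sets 1 and 2) and LIN28A 2.97-fold. CRIPTO, a Nodal co-receptor gene, fell 2.51-fold, a value limited by background because it was above it on 1 of the 2 shRNA arrays, and SALL3, not above background on either shRNA array, was at least 1.48-fold lower. Adjusted over the list alone, 11 fell and 1 rose. MYC, at a log2 change of -0.03, did not pass; MYC, PCNA and BBC3 were chosen for mention after their values were seen. NANOG, CRIPTO and SALL3 were dim on the arrays, NANOG being above background on both control arrays and 1 shRNA array. LIN28A was brighter, at 10.7 in the control, and MYC was at 15.7 in both groups. Some markers of other lineages fell too, although none of those lists passed. Of 17 T cell markers 9 fell and 0 rose (adjusted p = 0.052; 0.78 with an estimated correlation), and of 14 fibroblast and epithelial markers 6 fell and 1 rose (adjusted p = 0.118; 0.78 with an estimated correlation). Of 14 erythroid and megakaryocyte markers 5 fell and 1 rose (adjusted p = 0.37), and of 11 B cell markers 3 fell and 0 rose (adjusted p = 0.67).

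The mean difference from other genes in sets 1 and 2 was 0.35 and 0.62 for the p53 target genes, 0.30 and 0.54 for DNA replication, 0.23 and 0.49 for the pro-apoptotic list, 0.27 and 0.54 for the anti-apoptotic list and -0.40 and -0.61 for the pluripotency list. Set against 10000 random lists matched on signal, the median change of the pluripotency list stood at the 0.50th percentile, whereas the 4 rising lists stood between the 86.8th and the 96.4th, a comparison chosen after seeing the data. The median of the pluripotency list, a log2 change of -0.67, was the value of SALL4, the targeted gene. Without vector control replicate 2, in the fit without the block, none of the 5 passed (adjusted p = 0.11 to 0.53, camera). Their mean difference from other genes was then 0.27 in place of 0.49 for the p53 target genes, 0.23 in place of 0.42 for DNA replication, 0.10 in place of 0.36 for the pro-apoptotic list, 0.24 in place of 0.41 for the anti-apoptotic list and -0.32 in place of -0.51 for the pluripotency list. For the pro-apoptotic list it was 0.23 without shRNA replicate 1 and 0.62 without control replicate 1. A stricter filter kept transcripts above the 99th percentile of the random-sequence probes on all 4 arrays. With it none of the 4 rising lists passed (adjusted p = 0.34 to 0.65, camera). The mean difference was then 0.14 for the p53 target genes, 0.19 for DNA replication, 0.13 for the pro-apoptotic list and 0.12 for the anti-apoptotic list. The pluripotency list did not pass with median polish (adjusted p = 0.075), the authors' deposited normalized table (0.093), the deposited call files (0.051) or without shRNA replicate 1 (0.052). The anti-apoptotic list did not pass with median polish (0.052), the call files (0.051) or without shRNA replicate 2 (0.051), and the pro-apoptotic list with the normalized table (0.059), the call files (0.055) or without shRNA replicate 1 (0.12).

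**Figure D2:**
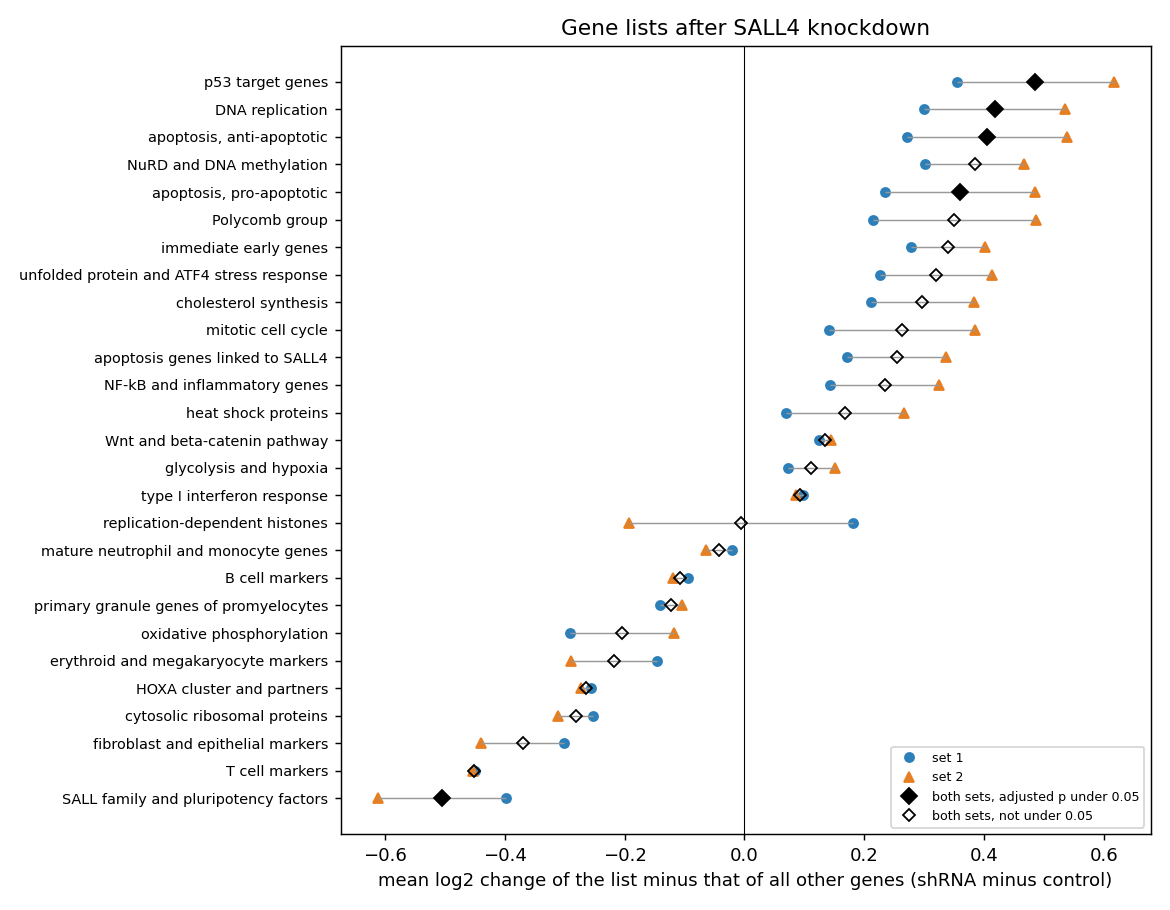
Mean log2 change, shRNA minus control, of each gene list minus that of all other genes (horizontal axis), in set 1 (circles), set 2 (triangles) and both sets (diamonds; filled where the adjusted p of camera with the preset correlation is under 0.05). The p53 target list has the highest joint value and the SALL family and pluripotency list the lowest.

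Among 13 apoptosis genes that published work on this cell line links to SALL4, 2 rose and 11 did not pass, both over all transcripts and adjusted over the list alone (adjusted p = 0.31 for the list, camera). That list was recalled from work that may have used these very arrays, so it is not independent evidence. CARD9, an adaptor of NF-kB signalling, rose 1.64-fold (adjusted p = 0.0021; log2 changes of 0.46 and 0.97 in sets 1 and 2). The log2 changes of ATF3, TNF, BCL2 and BMI1 were 0.45, 0.40, 0.39 and 0.31. Those of CYCS, DAD1, XIAP, LTA and TMBIM6 were -0.37, -0.15, -0.14, -0.07 and -0.06. Other transcripts disagreed with the brightest one for CYCS, where 1 of 5 rose and 2 fell, for XIAP, where 1 of 2 rose, for BCL2, where 2 of 3 rose, and for ATF3, where 2 of 4 rose.

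On the promoter array, which tiles 18028 regions of mostly 2.7 kb, the labels place SALL4 in Cy3 and IgG in Cy5, and ratios are given as SALL4 over IgG. The deposited log ratios run the opposite way (Pearson r = -1.0 with the ratios used here), so counts, list percentiles and the comparison with expression are also given with the sign turned. There was no replicate and no test. The highest 500 bp window of the array lay at the start of LINC01931, a long non-coding RNA gene (chromosome 2, region 150423451 to 150426151, window from -200 to 200 bp around the start; log2 ratio 2.86, 7.26-fold). The olfactory receptor genes OR5H2 and OR8D2 followed at 2.70 and 2.63. IRF8, a transcription factor of monocyte and B cell development (chromosome 16, region 84488074 to 84490774), had a window at 2.56 from 102 to 402 bp downstream of its start, and CD86, a co-stimulatory receptor of antigen-presenting cells, had one at 2.26 around its start. RAB17 and PCDHB5 stood at 2.56 and 2.44. The class II gene HLA-DQB2, the phosphodiesterase gene PDE5A, the cadherin gene DCHS2, the melanocortin receptor gene MC5R, MCMDC2, the actin-severing protein gene SCIN, GALNT1 and MORC1 stood between 2.27 and 2.21. The remaining regions of the 20 highest that could be named were lower: GKN2, KLHDC7A, the translation initiation factor gene EIF3E, the shared promoter of the type IV collagen genes COL4A5 and COL4A6, and OVGP1 stood between 2.19 and 2.13. Of these 20 regions, 10 were again among the highest 20 with 1000 bp windows and 14 after loess. With the sign turned, these windows are the ones lowest for SALL4.

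In all, 1638 of 17969 promoters (9.12%) had a window at least 2-fold higher for SALL4, and 4163 (23.2%) had a window at least 2-fold higher for IgG, 2.54 times as many. The highest windows of the sign-turned direction were in ADGRA1 at -3.63, CIMAP1A at -3.61 and NXNL2 at -3.36, regions chosen after their values were seen. The excess changed with processing: after loess within the array 2080 promoters were high for SALL4 and 810 for IgG, and after normexp 3451 and 3300. The mean log2 ratio was -0.23 in the bin from -100 to 200 bp around the transcription start and 0.11 between -2200 and -1900 bp, and after loess these means were -0.05 and 0.15.

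**Figure D3:**
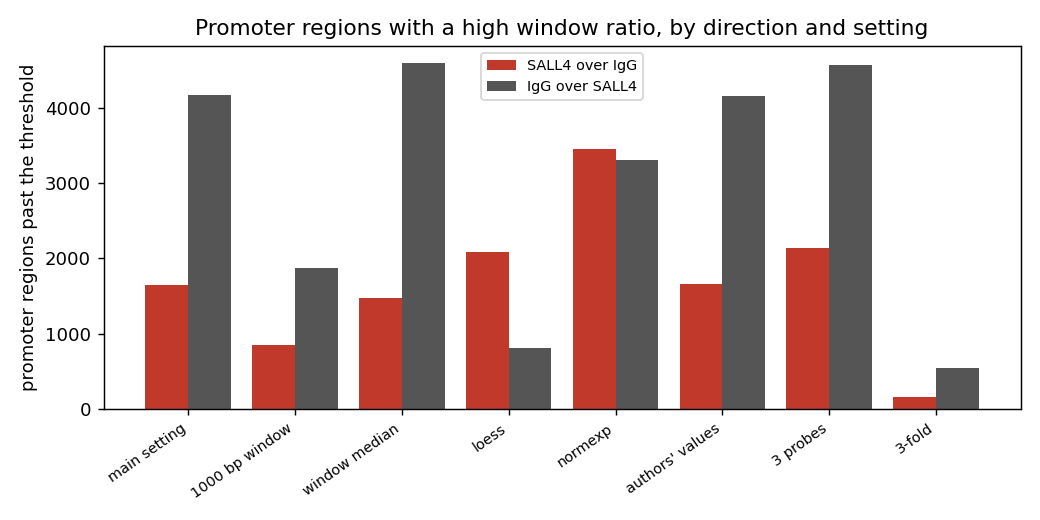
Number of promoter regions (vertical axis) with a window past the threshold for SALL4 over IgG (red) and for IgG over SALL4 (grey) on the single promoter array, under the main setting and 7 alternatives. The IgG count of 4163 exceeds the SALL4 count of 1638 in the main setting, and after loess the order is 810 against 2080.

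**Figure D4:**
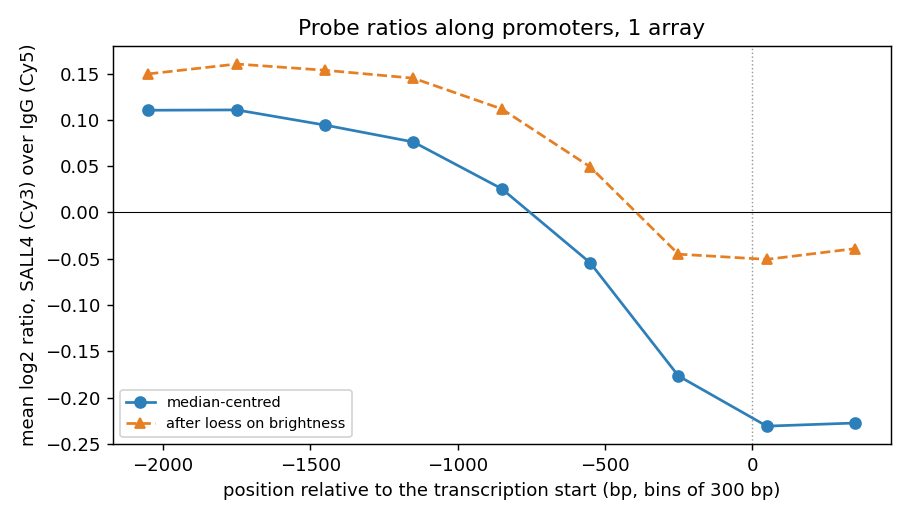
Mean log2 ratio of SALL4 (Cy3) over IgG (Cy5) per probe (vertical axis) by position relative to the transcription start in bins of 300 bp (horizontal axis), median-centred (circles) and after loess on brightness (triangles), over 15867 regions with 1 start. The median-centred mean goes from 0.11 in the most upstream bin to -0.23 around the start.

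The promoter of SALL4 itself (chromosome 20, 49851921 to 49854621) had a highest window of 1.29, a 2.45-fold ratio at the 97.1th percentile of all regions, and its lowest window was 0.35. BCL2 had a window at 1.16 together with one at -1.74, and BMI1, a Polycomb gene, had its highest at 0.89, the 85.9th percentile. With the sign turned, the SALL4 and BMI1 promoters stood at the 1.45th and 25.4th percentiles. For the other SALL4-linked apoptosis genes the highest windows ran from -0.46 (CYCS) to 0.71 (DAD1). Toward IgG, XIAP, LTA and TMBIM6 had windows at -2.13, -1.89 and -1.27. The median highest window of the list, 0.24, stood at the 20.1th percentile of 10000 random lists matched on probe number and intensity, and with the sign turned at the 84.9th. The latter was 99.2 with window medians, 99.9 after loess and 99.7 after normexp. Among the 27 lists, fibroblast and epithelial markers and replication-dependent histones had the highest percentiles toward SALL4, 99.9 and 95.8, with medians of 0.84 and 0.68. After loess neither was at or above the 95th, at 87.9 and 56.5, and T cell markers (99.5) and the SALL family and pluripotency list (95.6) were. With the sign turned, the first pair stood at 9.06 and 37.98, and after loess the second pair stood at 29.9 and 81.5. DNA replication genes had the highest percentile with the sign turned, 99.1, with a median of 0.93, but 93.2 after loess, and the SALL4-linked list stood above them with window medians, after loess and after normexp.

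A difference between genes with a high SALL4 promoter ratio and other genes after knockdown was not past the threshold in the main setting. Of the 406 measured genes among the top 500 promoters, 85 rose and 127 fell, against 3376 and 3317 of 16135 other genes, and the mean log2 change was lower by a difference of -0.12 (p = 0.088, camera; p = 0.16 with an estimated correlation), and by -0.08 in set 1 and -0.16 in set 2. Leaving out 1 array gave differences from -0.17 (without control replicate 1) to -0.07 (without control replicate 2). Their median signal was lower, 9.04 against 9.88. Against 10000 random gene sets matched on signal, with a median of 0.02, their median change of -0.06 stood at the 1.22th percentile, a comparison chosen after seeing the data. Ranked by the mean ratio over the whole region, the difference was -0.24 (p = 9.0e-04, camera; p = 0.23 with an estimated correlation), and with the sign turned it was 0.08 (p = 0.24). Of the 10 genes with the highest windows whose transcripts passed, OVGP1, an oviductal glycoprotein gene, rose 1.89-fold, FAM13B 1.60-fold and PDE5A 1.56-fold, the last limited by background because it was above it on 1 of 2 arrays of each group. The other 7 were not above background on either shRNA array: PCDHB5, OR8D2, NTM, GKN2 and SCIN were at least 1.54-fold, 1.39-fold, 1.31-fold, 1.17-fold and 1.13-fold lower, and no fold can be given for COL4A6 and ADAMTS1.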

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

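Cyclic loess, transcripts above a mean log2 signal of 11, signal-matched lists and the sign-turned promoter ranking were chosen after seeing the data. The count of 17894 transcripts became 0 without the block (7179 at an unadjusted p under 0.05, limma), 31311 with scaling to 1 median, 7195 with the deposited call files, 4696 with the stricter filter and 3711 above a signal of 11. With 1 array left out, in the fit without the block where the lone array is assumed to vary like the other group, it ranged from 1 (without control replicate 2) to 1777 (without control replicate 1), and rises were 0% to 20.3% of these calls. The stricter filter and the signal limit tested fewer transcripts; for the other settings the cause was not tested. Of the calls, 53.5% were rises, against 73.0% with scaling to 1 median, 45.5% with cyclic loess and 39.1% with the deposited call files. Among brighter transcripts rises were 70.8% of the calls with the stricter filter and 73.5% above a signal of 11. The other settings stayed within 1.5 times the count.

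The log2 change of SALL4 kept its sign. Its call was lost without the block (-0.67), with median polish (-0.32) and with the deposited normalized table (-0.60), and in all 4 fits with 1 array left out, where the change ran from -0.98 to -0.35 (adjusted p = 0.12 to 0.98, limma). The other SALL4 transcript, which had not passed, passed with scaling to 1 median (-0.49), cyclic loess (-0.50), no filter (-0.47) and the deposited normalized table (-0.72). SALL4 was not kept by the stricter filter. The cause was not tested.

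The 5 lists past the threshold became 11 without the block, 9 without background correction, 16 with scaling to 1 median, 9 with median polish, 12 without a filter, 3 with the stricter filter, 10 with cyclic loess and 9 with the mean of a gene's transcripts. With an estimated correlation, a test that rests on 1 residual degree of freedom, the number was 0. Of the 27 lists, 4 had medians outside the central 95% of signal-matched lists, and 1 of these, the pluripotency list, was among the 5. With 1 array left out the number of lists past the threshold ranged from 2 to 13. Of the 5 lists themselves, 3 passed with median polish, 3 with the deposited normalized table and 2 with the call files, and 5, 4, 3 and 0 without control replicate 1, shRNA replicate 2, shRNA replicate 1 and control replicate 2. With the stricter filter the SALL family and pluripotency list had too few genes, and the other 4 lists had adjusted p-values of 0.34 to 0.65 (camera).

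The difference of genes with a high promoter ratio was past the threshold with scaling to 1 median (-0.20) and with the mean over the whole region (-0.24), and with 1 array left out it ran from -0.17 to -0.07. It was positive with the stricter filter (0.0445) and, by construction a different set of genes, with the sign-turned ranking (0.0811). The count of 1638 promoters became 842 with 1000 bp windows, 3451 with normexp and 160 at 3-fold. The number of lists at or above the 95th percentile toward SALL4 was 2 in each setting run, but the lists changed: both were shared with normexp and the deposited log ratios, 1 with window medians and 1 with 1000 bp windows (replication-dependent histones each time), and 0 after loess. Of 61 named transcripts 51 had a call in the main fit, and all 51 lost it without the block, where no transcript passed. The other 10 had not passed in the main fit.

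Signs changed for named genes that had not passed. Scaling to 1 median, which moved the median of all transcripts from 0.12 to 0.58 and so lifts genes broadly, gave log2 changes of 0.91 for TMBIM6, 0.85 for DAD1, 0.68 for CYCS, 0.28 for LTA and 0.0701 for XIAP, and the deposited normalized table gave 0.0319 for TMBIM6. With 1 array left out the ranges were -0.21 to 0.0820 for TMBIM6, -0.34 to 0.0334 for DAD1, -0.0516 to 0.66 for BMI1, -0.10 to 0.89 for TNF, -0.39 to 0.25 for LTA and -0.33 to 0.0440 for XIAP. Signal over background limits SALL4, which lay near the random-sequence probes.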

Other observations

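Neither the list of ribosomal proteins nor that of respiration passed, but some members fell. Of 46 cytosolic ribosomal protein genes 16 fell and 0 rose (adjusted p = 0.068, camera; adjusted p = 0.78 with an estimated correlation; adjusted over the list alone, 16 fell). RPL38 had a log2 change of -0.88, RPS19 of -0.86 and RPS21 of -0.81. Of 41 oxidative phosphorylation genes 8 fell and 0 rose (adjusted p = 0.18, camera; adjusted p = 0.82 with an estimated correlation; adjusted over the list alone, 8 fell), among them NDUFA1 at -0.91 and COX7C at -0.85. With the signal-matched lists, both medians were below all 10000 random ones. In the HOXA cluster and its partners, 9 of 21 genes fell and 0 rose (adjusted p = 0.18, camera; adjusted over the list alone, 9 fell), with HOXA7 at -1.62 and HOXB3 at -0.73. These genes were chosen for mention after their values were seen.

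Myeloid genes moved both ways. Of 30 mature neutrophil and monocyte genes 3 rose and 8 fell (adjusted p = 0.79, camera; adjusted over the list alone, 3 rose and 8 fell): the integrin gene ITGAM rose by a log2 change of 0.80 and the G-CSF receptor gene CSF3R by 0.62. The 4 largest falls were of genes not above background on either shRNA array: S100A12, FCGR3B, CXCR1 and MMP8 were at least 1.91-fold, 1.85-fold, 1.45-fold and 1.12-fold lower. All myeloid genes named here were chosen after their values were seen. Of 16 primary granule genes of promyelocytes 1 rose, the lysozyme gene LYZ at 0.73, and 4 fell, among them RNASE2 at -0.85 (adjusted p = 0.59, camera; adjusted over the list alone, 1 rose and 4 fell).

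The tests of genomic DNA, background, germline genes, 5' sequence and dye labels were chosen or changed after results were seen, and those of normalization and dye bias were written before. Repeated gene families were lower on the shRNA arrays, with raw log2 medians in sets 1 and 2 of -3.59 and -3.03 for GAGE and -3.33 and -3.24 for REXO1L, but -1.36 and -1.47 for USP17L. A higher background of the control arrays, of a kind that random-sequence probes share, is argued against as the only cause. Single-copy receptors fell further than those probes, by -1.22 and -0.74. Unspecific signal that receptor probes pick up and random-sequence probes do not is outside this comparison and stays open. Single-copy germline genes did not fall further than the receptors, lying above them by 0.65 and 0.34. This cannot decide whether germline genes fell after knockdown, because the receptors were low themselves and the classes were not matched on signal. The raw medians of the germline genes, -1.04 and -1.13, were below those of all transcripts, -0.40 and -0.60. Genomic DNA in the control RNA may contribute and stays open: other silent multi-copy families differed from the receptors by 0.00917 and -0.08, but they were brighter than the receptors on the shRNA arrays by 0.40 and 0.27, so DNA in all arrays could level the change.

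Many transcripts of middle signal rose on the shRNA arrays. Loss of 5' sequence in the control RNA may contribute and stays open. The median change of rising transcripts was 0.60 from the 2 most 3' probes and 0.76 from the 2 most 5' probes, a ratio of 0.781, but they were called from the mean of these same probes, and over all kept transcripts the medians were 0.02 and 0.20, a ratio of 0.111. The choice of normalization stays open. Under scaling to 1 median 96.6% of the rising calls were again rising calls, which had been set beforehand as speaking against it, but that scaling itself moved the median of all transcripts from 0.12 to 0.58 and so nearly fixes the outcome, while cyclic loess kept 78.2%. An effect of SALL4 reduction is also open, and was not separated here from a difference in RNA quality.

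More promoters were high in the IgG channel than in the SALL4 channel. A dye bias that depends on brightness may contribute: the median log2 ratio went from 0.49 in the dimmest probes to -1.11 in the brightest, and after loess the IgG count was 0.389 times the SALL4 count. Loess removes any trend with brightness whatever its source, so this drop does not single out the dyes. After normexp on each channel, without loess, the IgG count was 0.956 times the SALL4 count. Exchanged dye labels cannot be told apart from a dye bias here. The SALL4-linked apoptosis genes stood at the 84.9th percentile toward IgG in the median-centred ratios. After loess they stood at the 99.9th and after normexp at the 99.7th, past the 95th that exchanged labels would need. That list was recalled from work that may have used this very array, so its percentiles are not independent evidence on the labels. The SALL4 and BMI1 promoters stood at the 97.1th and 85.9th toward SALL4 as labelled. A single array without a dye swap leaves both explanations open.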
